A study of Homo sapiens with 5 samples.

How the data were processed

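The series measured poly(A)-selected RNA of PC9, an established human lung adenocarcinoma cell line with an activating EGFR mutation. Per the labels' protocols, RNA was isolated with TriZol and libraries were made with a stranded mRNA kit. The labels give 3 parental libraries and 2 libraries of cells kept in 50 nM gefitinib, an EGFR kinase inhibitor, for 6 days and then in growth medium for 3 days. The labels do not say whether replicates came from separate cultures, so each gene's p-value measures only the spread between these libraries, which may be technical. List p-values compare the members with other genes, and chi-square p-values allow for counting error only. Neither of these kinds measures a spread between libraries.

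Per the submitters' processing notes, FastQC, STAR, DESeq2 and the human build hg38 were used. Their versions and settings, the counting tool and the annotation are not given in the sources used here. The authors' deposited table has 27477 genes and the columns of a DESeq2 result. The mean level was deposited by the authors as a signal, the mean over all libraries of reads divided by each library's size factor. Log2 fold changes and their standard errors were deposited by the authors on the log2 scale. The Wald score was deposited by the authors as the log2 fold change over its standard error, and the ratio recomputed from the columns differed by at most 1.8e-07. The p-values and adjusted p-values were also deposited by the authors. The adjusted values equalled a Benjamini-Hochberg adjustment over the 15223 genes that have one, to within 2.0e-05, and the smallest mean level among those genes was 8.23. The deposited fold changes were moderated towards 0. Among 996 genes with reads in drug-tolerant libraries only, the median was 0.11 and the highest 0.78, so fold changes of low genes are understated.

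Because the table has no values per library, no single gene was tested from reads, and the alternatives only rescaled or adjusted again the deposited scores and p-values. The test fixed before the data were examined for such a table was the authors' adjusted p under 0.05, and a "called" gene has this meaning unless an alternative is named beside it, while a called list has a list FDR under 0.05. The test planned for counts, edgeR's quasi-likelihood test, was not run for the same reason. Genes to be named were also fixed before the data were examined. They were the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among called genes with a mean of at least 100 in the higher group and a symbol that is not a clone, pseudogene or antisense name, together with 22 fixed genes and up to 4 members of each list with the smallest adjusted p and a mean of at least 10. The mean of the higher group was estimated from the deposited mean and fold change. The further condition that every library of 1 group lie above every library of the other could not be evaluated. Some genes are not reported here by name, and none was removed from a count or list test for that reason. Genes named outside this rule were chosen after their values were seen, and this is said where they appear.

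The sign of the fold change was settled from the values. A low gene's mean is a sum of whole reads times 5 steps, 1 for each library. All 12705 genes with a mean under 10 were resolved into whole reads in exactly 1 way within a tolerance of 1.5e-09, with a largest residual of 5.2e-10. On simulated libraries the procedure recovered 100% of 11309 genes. Reads in 3 of the 5 libraries pulled the fold change below 0 and reads in 2 pulled it above 0, which matches the numbers of parental and drug-tolerant libraries. Positive values are therefore higher in drug-tolerant cells. The sign of the difference computed from the recovered reads equalled the deposited sign in 98.9% of these genes. The recovered libraries were named parental a, b and c and drug-tolerant a and b, and could not be matched to replicate numbers. Size factors ran from 0.789 to 1.19. Multiplied by the total of the mean levels, 18.0 M reads, they give depths of about 14.2 to 21.4 M counted reads per library. The median standard error of the log2 fold change was 0.31 over the genes with an adjusted p.

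In all, 46 gene lists were fixed before the data were examined. They were tested with the cameraPR function of limma 3.58.1 in R 4.3.3 on the Wald score, with a preset inter-gene correlation of 0.01, where at least 5 members had an adjusted p. This held for 41 lists, and Benjamini-Hochberg adjustment over them gave the list FDR. An estimated correlation needs values per library and was not computed, so preset values of 0.05 and 0.2 were tried in its place. On simulated scores with 200 genes changed by 6 units among 15223 and a trend with length, the adjusted scores recovered 100% of the changed genes. In the same simulated scores 5.21% of the calls were false. The simulated noise was narrower than the real scores, whose robust SD was 1.50, or 1.16 after the trend was removed. That rate therefore does not carry over to calls on the real scores. With a shift of -1.5 simulated in a single list over the 15223 genes, that list was called and 0 others were. Those scores were drawn independently and without a trend, so this result gives no error rate for lists in the real scores.

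Gene identifiers were matched to GENCODE v29 on GRCh38 (27293 of 27477) and to a table of current symbols (27082). Of the symbols deposited, 23 had been turned into dates and 9774 rows had no symbol, so names were taken from the identifiers. Transcript length and GC content were those of the longest protein-coding transcript, or of the longest transcript where a gene has none, and 99.6% of tested genes had a value. As an alternative chosen after seeing the data, a loess trend on log10 length and GC (span 0.3) was subtracted from the Wald score and, separately, from the log2 fold change. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used for the other steps. Other alternatives were further thresholds, filters on the mean level, scores rescaled by their robust SD, ranks, fold changes in place of scores, and omission of rows inside ribosomal DNA repeats.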

Results

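RNA-seq was used to compare PC9 cells left after gefitinib with untreated parental PC9 cells. PC9 is a lung adenocarcinoma line that depends on mutant EGFR, the target of gefitinib. There were 3 parental and 2 drug-tolerant libraries, the latter from cells given 50 nM gefitinib for 6 days and growth medium for 3 days. Values are those of the authors' deposited table, in which positive log2 fold changes are higher in drug-tolerant cells and errors are the authors' standard errors. At a depth of about 14.2 to 21.4 M counted reads per library, 15223 genes had an adjusted p.

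The authors' deposited table called 40 genes higher in drug-tolerant cells at an adjusted p under 0.05 (DESeq2). DMBT1, a secreted scavenger receptor of mucosal epithelia on chromosome 10 (122560665 to 122643736, GRCh38; ENSG00000187908), rose 10.1-fold in the authors' deposited table, with a log2 fold change of 3.34 ± 0.40 (SE) and an adjusted p of 1.3e-12. IL1RL1, the receptor of interleukin 33 (chromosome 2, 102311502 to 102352037; ENSG00000115602), followed in the authors' deposited table at 1.89 ± 0.36 with an adjusted p of 0.00033. SLC6A14, an amino acid transporter, was at 1.80 ± 0.37 and C11orf86 at 1.74 ± 0.34 in the same authors' deposited table. CST4, a salivary cystatin, rose by 1.64 ± 0.36 in the authors' deposited table, and its reads can be shared with near-identical cystatin paralogs.

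Both CYP26B1, which degrades retinoic acid, and DHRS9, a dehydrogenase that acts on retinol and steroids, rose, by 1.53 ± 0.33 and 1.51 ± 0.28 in the authors' deposited table. MYH15 at 1.51 ± 0.40, the hyaluronan synthase HAS3 at 1.45 ± 0.29 and the pyruvate carboxylase gene PC at 1.40 ± 0.31 completed the 10 largest increases among called genes with a mean of at least 100 in the higher group in the authors' deposited table. Among fixed lists of signalling genes, the authors' deposited table also called the receptor FGFR1 (1.15 ± 0.26), the WNT antagonist SFRP1 (1.23 ± 0.24), the TGF-beta co-receptor TGFBR3 (1.21 ± 0.29) and the interferon-induced OAS1 (1.16 ± 0.26).

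The authors' deposited table called 44 genes lower. EEF1A2, a tissue-restricted translation elongation factor (chromosome 20, 63488012 to 63499322; ENSG00000101210), fell by 1.96 ± 0.34 on the log2 scale in the authors' deposited table, with an adjusted p of 4.0e-05. INSIG1, a sterol-regulated brake on cholesterol synthesis (chromosome 7, 155297776 to 155310235; ENSG00000186480), fell by 1.71 ± 0.33 in the authors' deposited table (adjusted p 0.00036), and SCD, the stearoyl-CoA desaturase, by 1.40 ± 0.35 (adjusted p 0.024). INHBA, which encodes an activin subunit, fell by 1.33 ± 0.22 in the authors' deposited table with an adjusted p of 9.7e-06, and ID3, a BMP and TGF-beta target, by 1.44 ± 0.39 with an adjusted p of 0.048. Hair keratin KRT81 (-1.60 ± 0.40) and the acute phase gene SAA1 (-1.52 ± 0.35) were lower in the authors' deposited table, with KRT81 and SAA1 each having a close paralog that can share reads. RAB32 (-1.43 ± 0.36), the GDNF-family ligand ARTN (-1.37 ± 0.36) and TRAPPC6A (-1.36 ± 0.35) were also among the 10 largest decreases at the same minimum mean in the authors' deposited table, and the glycolytic ALDOC was at -1.26 ± 0.32. Of the 44 lower rows, 4 are clone-named rows that lie inside copies of 18S ribosomal RNA on chromosome 21, with a median of -1.01 in the authors' deposited table and together 5.21% of the total mean level. Of these, 3 have nearly the same mean level and fold change, so the 4 rows can hold the same reads and are not separate results.

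These counts depended on how the Wald score was scaled. After it was centred and scaled by its robust SD over all tested genes, 1 gene, DMBT1, was called higher and 0 lower, against 40 and 44 in the authors' deposited table.

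**Figure D1:**
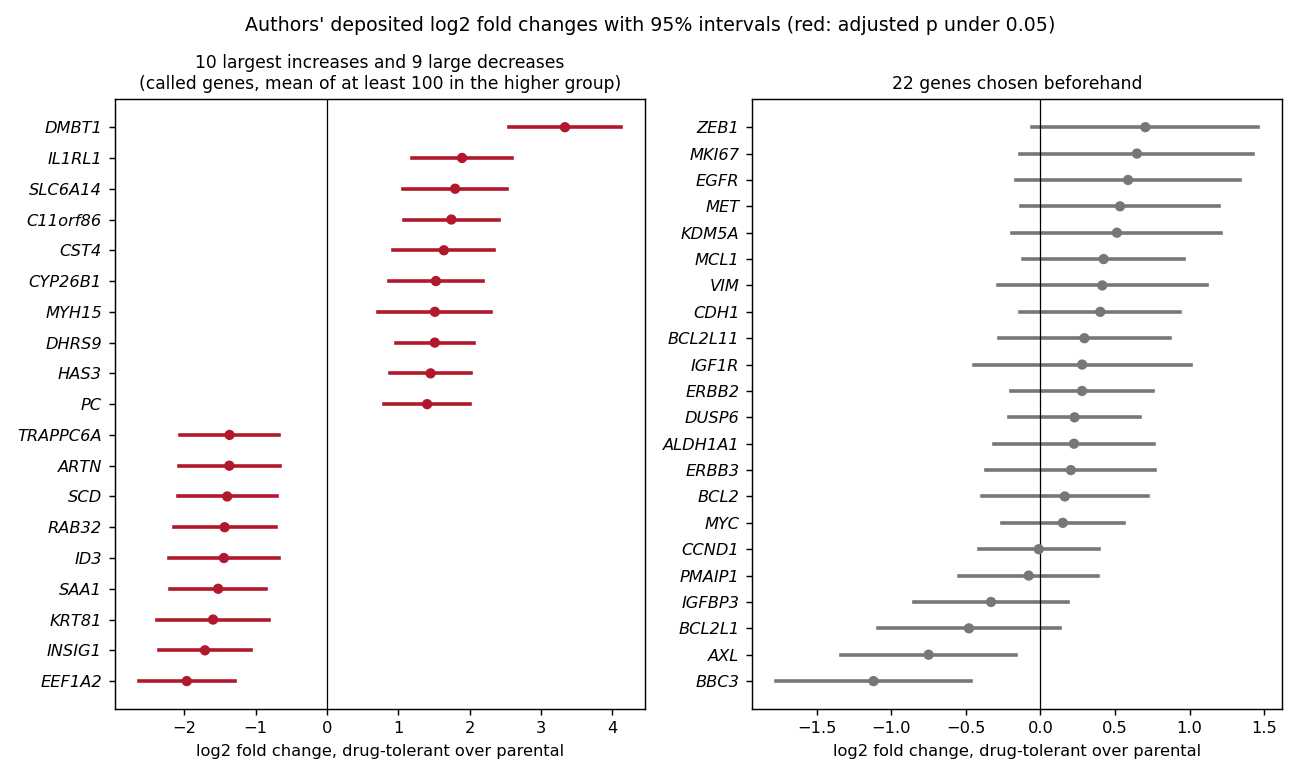
Log2 fold changes (drug-tolerant over parental, x axis) from the authors' deposited table for the 10 largest increases and 9 large decreases among called genes with a mean of at least 100 in the higher group (left) and the 22 genes fixed beforehand (right); bars are 95% intervals from the standard error, not adjusted for the number of genes. DMBT1 lies at 3.34 and EEF1A2 at -1.96, and 0 of the 22 fixed genes are red, the colour of an adjusted p under 0.05.

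None of the 22 genes fixed in advance as regulators of apoptosis, EGFR signalling and drug tolerance was called by DESeq2 in the authors' deposited table; 20 of them had an adjusted p. MCL1, an anti-apoptotic BCL2 family member, was at 0.42 ± 0.28 in the authors' deposited table (adjusted p 0.51; 95% interval -0.12 to 0.96). The other anti-apoptotic members with a row were BCL2L1 at -0.48 ± 0.31, BCL2 at 0.16 ± 0.28 and BCL2L2 at -0.30 ± 0.25 in the authors' deposited table, too few for a list test. Pro-apoptotic BBC3 was at -1.12 ± 0.33 in the authors' deposited table with an adjusted p of 0.088, BCL2L11 at 0.30 ± 0.29 and PMAIP1 at -0.08 ± 0.24. EGFR (0.59 ± 0.38), ERBB2 (0.28 ± 0.24), ERBB3 (0.20 ± 0.29), MET (0.53 ± 0.34), IGF1R (0.28 ± 0.37) and AXL (-0.75 ± 0.30) were not called in the authors' deposited table. Nor were the MAPK phosphatase DUSP6 (0.23 ± 0.22), the cycle genes CCND1 (-0.01 ± 0.20), MYC (0.15 ± 0.21) and MKI67 (0.65 ± 0.40), or IGFBP3 (-0.33 ± 0.26) in the authors' deposited table. The epithelial CDH1 was at 0.40 ± 0.27, the mesenchymal VIM at 0.41 ± 0.36 and the demethylase KDM5A at 0.51 ± 0.36 in the authors' deposited table, also not called. ZEB1 and ALDH1A1, with mean levels of 6.85 and 1.24 in the authors' deposited table, had no adjusted p.

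Cytosolic ribosomal protein genes had the lowest median of the 41 lists tested. All 45 tested members had negative values in the authors' deposited table, with a median of -0.77, and the list was lower by cameraPR with an FDR of 1.3e-18. Of the 45, 0 were called over all genes tested and 29 were lower when adjusted over the list alone. RPS18 was at -0.92 ± 0.34, RPLP2 at -0.99 ± 0.37 and RPL13 at -0.92 ± 0.35 in the authors' deposited table, and reads of such genes can be shared with their many processed pseudogenes. These transcripts are short, with a median length of 1170 nucleotides. The list median was -0.52 after the trend with transcript length and GC content was removed, with a cameraPR FDR of 1.3e-12. That removal took no account of mean level.

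The cholesterol synthesis list was lower too, with a median of -0.54 over 22 tested genes and a cameraPR FDR of 1.4e-07. INSIG1 was the 1 member called over all genes tested, and 10 members were lower when adjusted over the list alone, including HSD17B7 (-0.88 ± 0.25), TM7SF2 (-1.03 ± 0.31) and IDI1 (-0.82 ± 0.28) in the authors' deposited table. The list FDR was 1.7e-07 with the length and GC trend removed and 0.11 at a preset correlation of 0.2. In the fatty acid synthesis list SCD was called, and SREBF1 (-0.81 ± 0.23), FADS1 (-0.82 ± 0.25) and FADS2 (-0.74 ± 0.25) were lower when the authors' deposited table was adjusted over the list alone. Its 12 tested genes had a median of 0.013, a mean of -0.16 and a cameraPR FDR of 0.25, which became 0.0055 with the length and GC trend removed. The TGF-beta signalling list, with INHBA and ID3 lower and TGFBR3 higher, went from a cameraPR FDR of 0.15 to 0.025 on the same removal, with a median of -0.10 over 19 genes.

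Mitochondrial gene lists were lower with smaller medians. The nuclear oxidative phosphorylation list had a median of -0.41 over 30 genes (cameraPR FDR 0.0027), with COX7C at -0.84 ± 0.36 and COX6C at -0.81 ± 0.36 in the authors' deposited table. The 13 mitochondrially encoded genes had a median of -0.43 (cameraPR FDR 0.011), with MT-ND1 at -0.61 ± 0.35 and MT-ND2 at -0.59 ± 0.33 in the authors' deposited table. In both lists 0 members were called, over all genes tested or adjusted over the list alone. With the length and GC trend removed, the FDR was 0.027 for the nuclear list and 0.092 for the mitochondrially encoded one, and neither was called at a preset correlation of 0.05 (FDR 0.070 for each).

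Among the remaining lists called lower by cameraPR, NF-kB and inflammatory genes had a median of -0.36 over 19 genes (FDR 0.013), with SAA1 called and 3 lower when adjusted over the list alone, among them CXCL8 at -0.87 ± 0.32 in the authors' deposited table. Class I HLA and antigen processing genes had a median of -0.37 over 16 genes (cameraPR FDR 0.029), with HLA-E at -0.67 ± 0.25 and 0 called either way in the authors' deposited table. Lysosome and autophagy genes had a median of -0.20 over 30 genes (cameraPR FDR 0.029), with NPC2 (-0.86 ± 0.27), GABARAPL1 (-0.87 ± 0.28) and WIPI1 (-0.95 ± 0.32) of the authors' deposited table lower when adjusted over the list alone. CDK inhibitors and quiescence genes had a median of -0.37 over 14 genes (cameraPR FDR 0.038), with CCNG2 (-0.84 ± 0.23), CDKN1A (-1.01 ± 0.36) and CDKN2D (-1.06 ± 0.39) of the authors' deposited table lower when adjusted over the list alone. After removal of the length and GC trend the FDR was 0.025 for the inflammatory list, 0.075 for HLA class I, 0.092 for lysosome and autophagy and 0.049 for the CDK inhibitors. None of the 4 was called at a mean of at least 50 (0.052, 0.054, 0.052 and 0.058 in the same order) or at a preset correlation of 0.05 (0.11, 0.15, 0.17 and 0.15), lysosome and CDK inhibitor genes were not called on ranks (0.052 and 0.093), and HLA class I, lysosome and CDK inhibitor genes were not called on log2 fold changes (0.083, 0.058 and 0.053).

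Replication-dependent histone genes, whose main transcripts lack a poly(A) tail, were the 1 list called higher. In poly(A)-selected RNA, the reads of these genes may come from transcripts that carry a tail. The list median was 0.46 over 10 genes with a cameraPR FDR of 0.029. H2AC6 (1.11 ± 0.37) and H2BC12 (0.90 ± 0.31) of the authors' deposited table were higher when adjusted over the list alone. The list FDR was 2.0e-05 after the length and GC trend was removed, 0.057 on ranks, 0.26 with no filter on low counts, and 0.11 and 0.63 at preset correlations of 0.05 and 0.2, and the list had too few members to test at a mean of at least 50. The highest mean level among its members was 114, so the values rest on low counts, and reads of histone genes can be shared among near-identical copies.

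Of the 41 lists tested, 32 were not called. Receptor tyrosine kinases had a median of 0.27 over 17 genes and an FDR of 0.053 by cameraPR. With the length and GC trend removed their median was -0.06 and their FDR 0.79. Pro-apoptotic BCL2 family genes had a median of -0.37 over 11 genes and a cameraPR FDR of 0.053 as well (0.0045 to 0.63 over the alternatives), with 2 lower when adjusted over the list alone. Ligands of receptor tyrosine kinases had a median of 0.33 over 16 genes (cameraPR FDR 0.12), with HBEGF (0.75 ± 0.22) and EREG (0.82 ± 0.28) of the authors' deposited table higher when adjusted over the list alone. The drug-tolerant persister markers (median 0.24 over 13 genes, cameraPR FDR 0.77), ERK pathway output (0.08 over 19, FDR 0.42), mitosis and G2/M genes (-0.07 over 31, FDR 0.95), DNA replication genes (0.02 over 31, FDR 0.97), interferon-stimulated genes (-0.02 over 21, FDR 0.77) and mesenchymal genes (-0.0028 over 16, FDR 0.54) were not called. In 10 lists, all with an FDR over 0.05, the median, the mean and the direction of the test differed in sign. These were DNA replication, mitosis, mesenchymal, interferon-stimulated, fatty acid synthesis, FOXO target, translation initiation, ribosome biogenesis, squamous and neuroendocrine genes. Lists of fibroblast, haematopoietic and endothelial markers had 1, 2 and 3 tested members with 0 called. The endothelial marker PECAM1 had a mean level of 1616 and a log2 fold change of 0.57 ± 0.26 in the authors' deposited table, and the highest haematopoietic marker, ITGAM, a mean of 25.9. No correlation between genes could be estimated without values per library. With a preset correlation of 0.05 only ribosomal protein and cholesterol synthesis genes passed, and with 0.2 only ribosomal protein genes (cameraPR FDR 0.016).

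**Figure D2:**
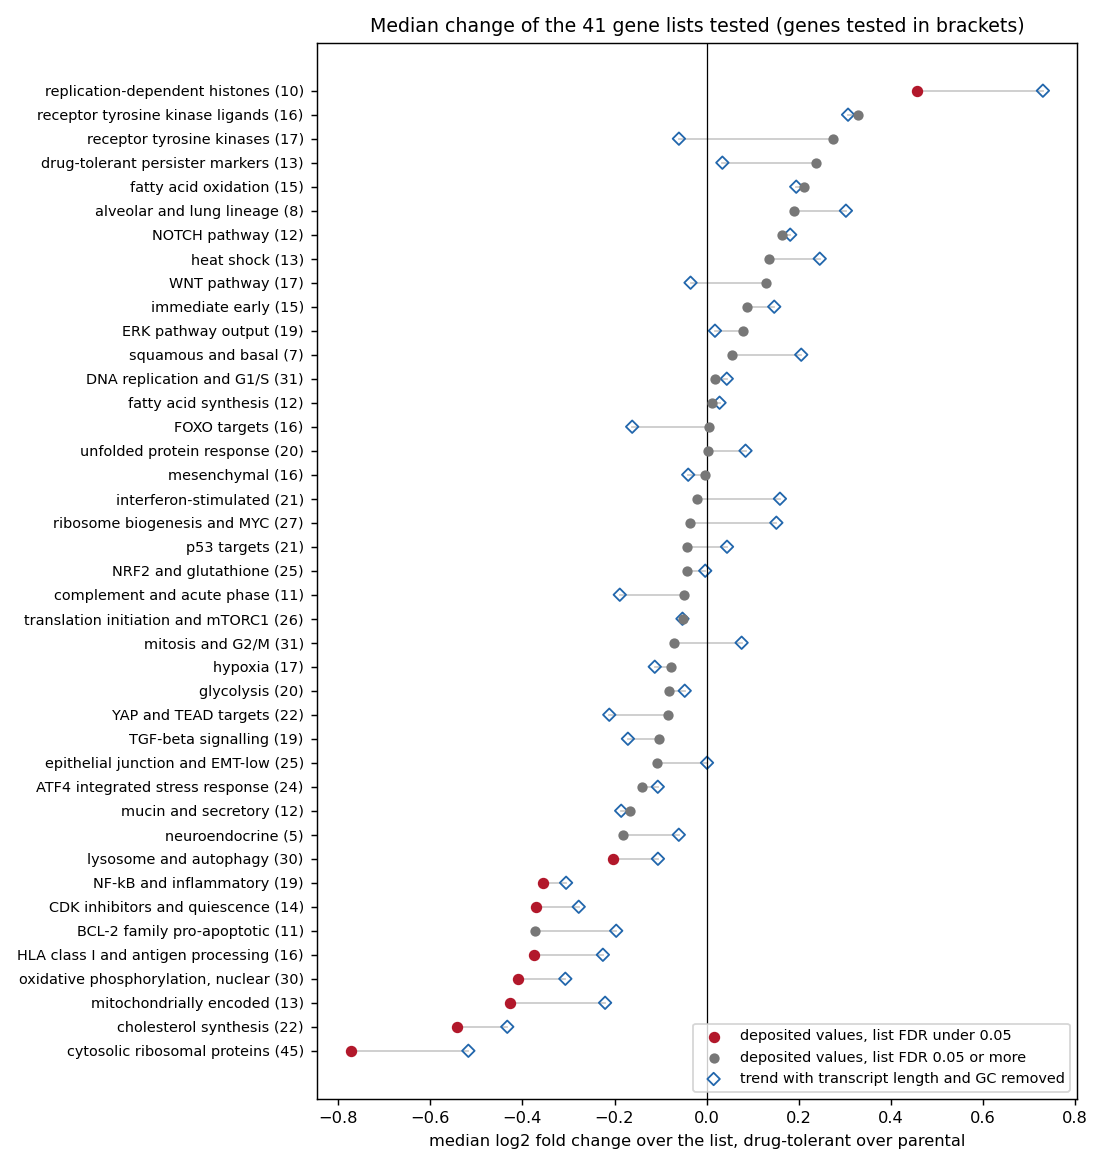
Median log2 fold change (x axis, drug-tolerant over parental) of each of the 41 gene lists tested, with the number of tested genes in brackets; filled points are from the authors' deposited values, red where the list FDR was under 0.05, and open diamonds show the median after the trend with transcript length and GC was removed. Ribosomal protein genes moved from -0.77 to -0.52 and receptor tyrosine kinases from 0.27 to -0.06.

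Fold changes followed transcript length across genes. Over the 12461 protein-coding genes tested with a length, Spearman's correlation between the log2 fold change of the authors' deposited table and transcript length was 0.54, computed across genes, which are not independent replicates. Of 10 groups of equal size by length, the shortest, of median length 1114 nucleotides, had a median log2 fold change of -0.50 and the longest, of median length 9552, 0.38. For GC content the correlation was -0.12. The length trend cannot be told apart from a split of the parental libraries. In genes with a mean under 10, reads of transcripts over 4 kb per read of transcripts under 2 kb were 0.974 in parental a. They were 0.998 and 0.880 in the drug-tolerant libraries, and 0.616 and 0.610 in parental b and c. The 38 protein-coding genes called higher had a median length of 3875 nucleotides and the 38 called lower 1998, against 3430 for those not called. With the trend removed, 42 genes were higher and 34 lower, of which 29 and 16 were among the genes called in the authors' deposited table. MYH15, KRT81, ID3, RAB32, ARTN and TRAPPC6A then lost their call, with adjusted p from 0.099 to 0.30, because their scores were smaller. Their log2 fold changes kept their sign and went from 1.51 to 1.24, -1.60 to -1.39, -1.44 to -1.12, -1.43 to -1.11, -1.37 to -1.18 and -1.36 to -1.02, with the deposited standard errors of 0.40, 0.40, 0.39, 0.36, 0.36 and 0.35.

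**Figure D3:**
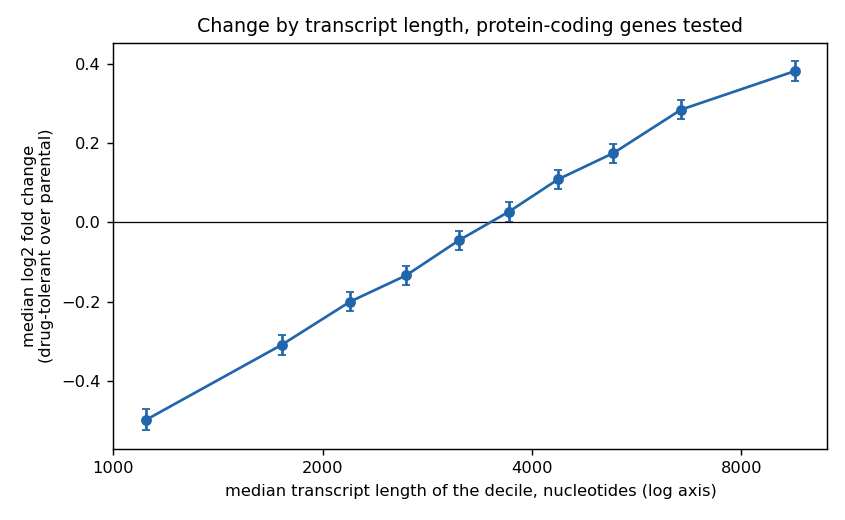
Median log2 fold change (y axis, drug-tolerant over parental) of protein-coding genes in 10 groups of equal size by transcript length (x axis, log scale, nucleotides); bars are 95% intervals of the median. The medians run from -0.50 to 0.38.

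The libraries did not separate by group in low-count genes. Reads were recovered for the 12705 genes with a mean under 10. Each pair of libraries was compared over those with at least 10 reads in the pair, 1390 to 2744 genes. The chi-square per degree of freedom was 1.05 (p = 0.095, 1423 genes) between parental libraries b and c, which agree within sampling noise there. Low counts cannot tell a single RNA from similar cultures, so parental b and c may be either. The authors' comparison counted them separately, and the deposited values cannot be recomputed with them as 1 sample. Between the drug-tolerant libraries the value was 1.11, between parental a and the drug-tolerant libraries 1.36 and 1.43, and between parental a and the other parental libraries 3.50 and 3.57, all beyond sampling noise. Sense-intronic genes stood at 1.32 times the mean of the 5 libraries in parental a, 0.61 and 0.63 in parental b and c, and 1.28 and 1.16 in the drug-tolerant libraries. Reads of transcripts over 4 kb per read of transcripts under 2 kb were 0.974 in parental a, 0.616 and 0.610 in parental b and c, and 0.998 and 0.880 in the drug-tolerant libraries. Parental b and c hold parental cells only and parental a is a single library. No value within libraries that lie together was computed for the genes and lists above, because reads per library were recovered only for genes with a mean under 10.

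**Figure D4:**
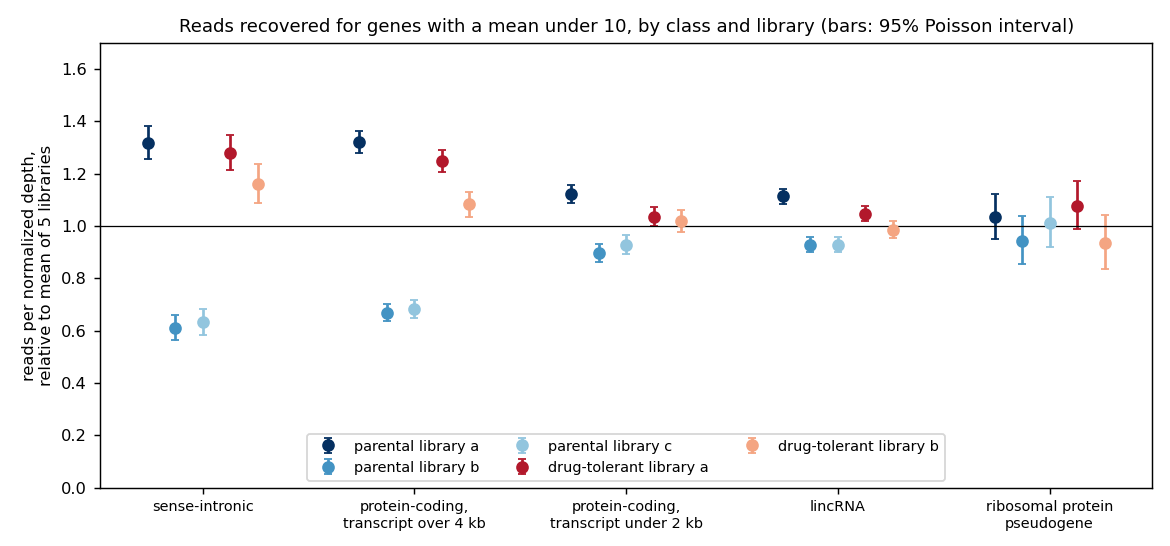
Reads recovered for genes with a mean under 10, per normalized depth and relative to the mean of the 5 libraries (y axis), by gene class (x axis) and library (colours); bars are 95% Poisson intervals and cover counting error only. For sense-intronic genes parental a lies at 1.32 beside the drug-tolerant libraries at 1.28 and 1.16, while parental b and c lie at 0.61 and 0.63.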

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

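The filters on mean level, the thresholds of 0.01 and of 1 on the log2 fold change were chosen before the data were examined, and the other alternatives after seeing the data. Against 40 genes called higher and 44 lower, an adjusted p under 0.01 left 25 and 14, an adjusted p under 0.1 gave 64 and 89, and scores scaled by their robust SD gave 1 and 0. With no filter on low counts 34 were higher and 26 lower, because more genes were tested, and MYH15, ID3, ARTN and TRAPPC6A were not called. The mean filter of 50, omission of the 18S rows and removal of the length and GC trend kept both counts within 1.5 times. Omission of the 18S rows gave 39 higher and 35 lower, and ID3 was not called. Against 1 list called higher and 8 lower, a mean of at least 50 left 0 and 5 (4 of the 8 among them, without the inflammatory, HLA class I, lysosome and CDK inhibitor lists and with pro-apoptotic BCL2 family genes added at an FDR of 0.037), a preset correlation of 0.05 left 0 and 2, and 0.2 left 0 and 1. With no filter on low counts the histone list was lost (FDR 0.26) and receptor tyrosine kinases were called in its place (FDR 0.022). Their FDR was 0.79 with the length and GC trend removed. Without the filter all 8 lower lists were kept, with pro-apoptotic BCL2 family genes (FDR 0.0045) and TGF-beta signalling (FDR 0.021) added, giving 10. The pro-apoptotic list was called in these 2 settings alone, with an FDR of 0.080 to 0.63 in the other 5. Ranks of the score called 0 lists higher, and log2 fold changes in place of the score called 5 lower. Where no construction explains a difference, the cause was not tested. With the length and GC trend removed, BCL2 turned to -0.13, PMAIP1 to 0.10, ERBB3 to -0.022 and IGF1R to -0.20, none of them called before or after. No paired analysis was possible because the table holds no values per library. Other normalizations, pseudocounts, refits with edgeR, DESeq2 or limma-voom, non-robust moderation, a test against a fold of 1.5, omission of each library in turn, fry and an estimated correlation were not run for the same reason. Depth limits genes with a mean under 8.23, which have no adjusted p.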

Other observations

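Some called genes outside the fixed rule, chosen after their values were seen and not tested as a group, were RARRES1 (-1.24 ± 0.24), SPP1 (0.96 ± 0.22), TIMP3 (1.04 ± 0.23), ADAM12 (1.31 ± 0.32) and KITLG (1.13 ± 0.29) in the authors' deposited table.

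Tests of the split of the parental libraries and of the 18S rows were chosen only after those results were seen. Those of the ribosomal protein genes were chosen before their own outcomes were seen. By then the decrease of these genes, the length trend and the split were already known.

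Parental library a lay nearer to the drug-tolerant libraries than to parental b and c in low-count genes, and still differed from both drug-tolerant libraries (chi-square per degree of freedom 1.36 and 1.43). Intronic and other background reads may contribute to this, since sense-intronic reads per normalized depth were 2.12 times as high in parental a as in the mean of b and c. The ratio was 1.95 for coding transcripts over 4 kb, 1.58 for antisense genes, 1.54 for processed pseudogenes other than those of ribosomal proteins and 1.23 for coding transcripts under 2 kb, and long intergenic RNAs differed least apart from ribosomal protein pseudogenes, so the split is nearly as large in long coding transcripts and does not single out intronic reads. A drug-tolerant library carrying a parental label cannot be told apart from this by the fold changes. A parental group with 1 library at the drug-tolerant level limits an increase to a fold of 3 and does not limit a decrease. Of the increases, 9 genes exceeded it as point values but 1, DMBT1, beyond its 95% interval. A difference between cultures of the parental cells was not tested.

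Ribosomal protein genes were lower as a list, with a median of -0.77. The trend with transcript length and GC could produce part of this, since 10000 random lists matched on length, GC and mean level had a median of -0.51, or -0.57 when matched on the principal transcript. Of the 10000 lists, 0 lay at or below the list median in either matching, and the lowest were at -0.68 and -0.74. The matched genes were longer (median 1409 against 1170 nucleotides, or 901 against 835 for the principal transcript) and had lower mean levels (median 8404 against 13412). Their lists were drawn gene by gene, so they do not have the spread of genes that change together. The count therefore does not exclude length, GC and mean level as the source of the whole. Whether the decrease follows parental b and c cannot be told apart from a change with gefitinib. Reads of ribosomal protein pseudogenes per read of other processed pseudogenes, relative to all libraries, were 0.879 in parental a, within the 0.864 and 0.900 of the drug-tolerant libraries and below the 1.24 and 1.31 of parental b and c. This came from the other processed pseudogenes, at 1.18, 0.76 and 0.77 of the mean of the 5 libraries in parental a, b and c per normalized depth. Ribosomal protein pseudogenes were at 1.03, 0.94 and 1.01, and their mean in drug-tolerant libraries was 1.03 times that of parental b and c, so these reads do not show the decrease and decide nothing about it.

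The 4 rows inside 18S ribosomal RNA, which can hold the same reads, were lower, with a median of -1.01. Less carry-over of RNA without a poly(A) tail would lower other such RNAs alike. The median of 46 of them was 0.043 with a bootstrap SE of 0.072, but they went both ways, with 11 snRNAs at a median of -0.49, 8 other ribosomal RNA rows at 0.043, 15 snoRNAs at 0.35 and the 10 histone genes called as a list at 0.46. Because the kinds of RNA differ in direction, this cannot be told apart from a change of ribosomal RNA in the cells. The 8 other ribosomal RNA rows did not share the decrease in their median, at 0.043 against -1.01 for the 18S rows. No spread is given for these 8 rows alone, so they do not decide whether ribosomal RNA changed in the cells. A change of 18S ribosomal RNA alone was not tested.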
